A study of Mus musculus with 2 samples.

How the data were processed

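RNA was measured by long-read sequencing, in which each read is meant to span a whole cDNA molecule, in adrenal gland tissue of 14-day-old female mice. The mice were B6CASTF1/J, the F1 cross between a C57BL/6 and a CAST parent. The labels give 2 libraries, biological replicates 1 and 2 of a single group, made from separately recorded tissue samples. The name of the replicate 1 tissue sample speaks of 3 females and that of replicate 2 of 1 female, while the descriptions of both libraries speak of 3. Replicate 1 may therefore be a pool and replicate 2 a single animal, which the labels leave open. Each tissue sample has 1 library, so the spread between tissue samples cannot be told from that of preparation and sequencing. There is no treatment, control or second group.

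Per the file headers, each library has a table with the read count of every transcript model that drew at least 1 read, and a transcript annotation on the mm10 assembly built on GENCODE M21. The deposited counts are whole reads, not scaled for depth or length, and the replicates were not pooled. Per the file headers, the models carry the identifiers and classes of the TALON program. Known models match an annotated transcript. ISM (incomplete splice match) models hold part of an annotated chain of introns. NIC models join annotated splice sites in an unannotated order, and NNC models have at least 1 unannotated splice site. Genomic models overlap a gene without matching its splicing, and Antisense and Intergenic models were given no annotated gene, though some merged loci of these classes overlap one on their strand. The aligner, the TALON version and any filter on reads are not given in the sources used here. The labels name Ambion mix 1 and Lexogen set 4 as spike-ins. The annotation tables hold 96 ERCC entries of the first and 0 SIRV entries of the second, so only ERCC reads were counted as spike-ins.

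Replicate 1 holds 1143111 reads and replicate 2 991731, of which 1065570 and 946553 fall in annotated genes. CPM values were computed over these gene reads without spike-ins, with every class counted for its gene. A gene with 0 reads was set a limit of 3 counts, 2.82 CPM in replicate 1 and 3.17 CPM in replicate 2. Shares have exact Clopper-Pearson 95% intervals. Reads without molecular identifiers are not independent molecules, so intervals, limits and tests on reads cover counting error only and compare these 2 libraries, not the animals behind them. Values over both libraries are given as mean ± SD (n = 2).

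Genes with at least 20 summed reads were compared between the libraries by an exact conditional binomial test, two-sided, given the totals of gene reads, with Benjamini-Hochberg adjustment at 0.05. Log2 ratios are of CPM in replicate 2 over replicate 1 with 0.5 reads added, and their SE is the counting error. Where a library held 0 reads, the fold is given against the limit of 3 counts in that library. This fold leaves out the counting error of the other library, so the exact counting interval can reach lower. Where a library held 1 to 3 reads, the ratio is given with its exact counting interval. Gene lists were summarised by the median log2 ratio of members with at least 20 summed reads and by its percentile among 10000 random lists of the same size matched on mean expression, where a list had at least 5 such members. Class shares were compared by Fisher's exact test with Benjamini-Hochberg adjustment over the classes. With an intercept only, edgeR gave a common dispersion of 0.217, a coefficient of variation of 0.466.

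For isoforms, Known transcripts were matched between the libraries by their annotated identifier, and NIC and NNC transcripts by gene and chain of introns. Genes with at least 20 reads in each library on 2 or more multi-exon transcripts of at least 5 summed reads were compared by a Monte Carlo permutation test of the transcript by library table with fixed margins (100000 draws, smallest p 1e-05), or Fisher's exact test for 2 transcripts. A second isoform counted as in use at 10% or more of a gene's reads in both libraries. A chain given one of these classes in either library was counted in both. This reading was chosen after results with each library's own class had been seen, because chains called ISM in one library and NIC in the other had been counted as 0 reads. Unannotated loci that overlap on a strand were merged across the libraries, likewise after some had been seen counted double.

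The tests, 21 gene lists, alternatives and the rule for the genes named in the text were fixed before the data were examined. The rule takes the 15 genes of highest mean CPM, the 4 measured members of highest mean CPM in each list and every member of lists under 7 genes, and the 10 largest log2 ratios in each direction among genes past the test with at least 50 summed reads. It also takes the 8 genes with most reads and a second isoform in use, 6 genes of an isoform panel with the lowest leading share, the 5 unannotated transcripts and 5 unannotated loci with most reads in both libraries, and the 5 largest isoform share differences past the test. One gene and one locus that the rule takes are not reported here. The lists cover steroid synthesis and cholesterol uptake, cholesterol synthesis, zona glomerulosa and capsule, X zone, medulla chromaffin cells, Schwann and sustentacular cells, endothelial cells, macrophages and other leukocytes, erythroid cells, adipocytes, kidney, liver and pancreas, proliferation, immediate early and stress genes, imprinted growth genes, X inactivation and Y-linked genes, mitochondrially encoded genes, the nuclear-encoded respiratory chain, cytosolic ribosomal proteins, antioxidant defence and the isoform panel. A hepatocyte set of 28 genes and a skeletal muscle set of 20 genes were added after the data had been seen.

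Reads of near-identical copies may be split between them by the authors' counting, so values are uncertain for Hba-a1 and Hba-a2, Hbb-bs and Hbb-bt, Cyp21a1 and its pseudogene, Cyp11b1 and Cyp11b2, Hsd3b1 and Hsd3b6, Serpina1a, Ugt2b36, Akr1c6, Akr1c18, C4b and ribosomal protein genes with processed copies. Single-exon reads on the strand opposite to a gene cannot be told from reads of that gene with a wrong strand call, since no splice site fixes their strand.

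The alternatives were scaling by TMM factors from edgeR, by DESeq2 size factors or by spike-in reads, other count minimums, an edgeR exact test with an assumed coefficient of variation of 0.2, Known transcripts only, ISM transcripts added, reads thinned to equal depth, other matching of unannotated transcripts, and each library alone. Each library's own class for isoforms, and list shares over reads without liver and muscle genes, were added after the data had been seen. The gene test was tested on simulated data of 9210 genes with 200 changed, the changed ones drawn from genes with at least 100 expected summed reads. It recovered 95 of 100 genes changed 2-fold and 100 of 100 changed 4-fold, and called 7 unchanged genes. The isoform test recovered 170 of 199 genes whose transcripts had been altered among 2530, with 8 unchanged genes called. Each alteration moved 50% of a gene's reads to 1 transcript in replicate 2, and the simulation used 10000 draws. Its recovery of smaller shifts was not measured. Both simulations held counting error only, with no further spread between libraries. They therefore do not measure how often the tests call genes because of such spread in the real libraries. Versions were R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.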

Results

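Adrenal gland tissue of 14-day-old female B6CASTF1/J mice was sequenced as 2 libraries, biological replicates 1 and 2 of a single group. Replicate 1 held 1143111 reads on 122134 transcript models and replicate 2 held 991731 reads on 99893 models. Reads in annotated genes numbered 1065570 and 946553, reads on unannotated loci 50647 and 29275, and spike-in reads 26894 and 15903. At least 1 read was seen for 16422 annotated genes in replicate 1 and 15952 in replicate 2. With no treatment or second group, the design asks which genes and isoforms the juvenile adrenal gland expresses and how closely a second library repeats the first. Every p-value below is from reads of these 2 libraries, n = 2 throughout, apart from the permutation tests of list medians, which shuffle genes.

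The most abundant transcripts were those of corticosteroid synthesis in replicate 1 and those of plasma proteins, usually made in liver, in replicate 2. Cyp11a1, which encodes the side-chain cleavage enzyme that opens steroid synthesis (ENSMUSG00000032323.13, mm10 chromosome 9, 57998041 to 58028677), had 21322 CPM in replicate 1 and 9021 CPM in replicate 2, 15172 ± 8698 (SD, n = 2). It ranked 1 in replicate 1 and 5 in replicate 2. Trf, which encodes transferrin (ENSMUSG00000032554.15, chromosome 9, 103204001 to 103228442), had 276 CPM in replicate 1 and 28907 in replicate 2, and Apoe had 1822 and 26307 CPM. Trf ranked 1 in replicate 2 and 649 in replicate 1. The 15 genes of highest mean CPM were Cyp11a1, Trf, Apoe, Alb, Cyp21a1, Akr1c18, Hsd3b1, Ahsg, Atp5b, Cyp11b1, Apoa1, Star, Cox4i1, Hba-a1 and Adh1. Of these, Cox4i1, a subunit of cytochrome c oxidase, repeated most closely, with 3881 and 3889 CPM (3885 ± 5.87 CPM, SD, n = 2). Adh1, an alcohol dehydrogenase, had 3948 and 2377 CPM, a log2 ratio of -0.73 (SE 0.038). The 10 leading genes took 8.24% of gene reads in replicate 1 and 12.3% in replicate 2.

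Genes of steroid synthesis and cholesterol uptake were lower in replicate 2. The list held 6.01% of gene reads in replicate 1 (95% interval 5.97 to 6.06) and 2.69% in replicate 2 (2.66 to 2.73), 4.35 ± 2.35% (SD, n = 2). Of 18 measured members 14 were lower in replicate 2, 1 was higher and 3 did not pass, and the numbers adjusted over the list alone were also 14 and 1. Cyp21a1, the steroid 21-hydroxylase (11998 and 5110 reads), had a log2 ratio of -1.06 (SE 0.024), Hsd3b1, a 3-beta-hydroxysteroid dehydrogenase (8617 and 3577 reads), of -1.10 (SE 0.029), and Cyp11b1, the 11-beta-hydroxylase (7421 and 3195 reads), of -1.04 (SE 0.031). Star, which carries cholesterol into mitochondria (6374 and 2232 reads), had a log2 ratio of -1.34 (SE 0.035). The lowest ratio was -1.59, of the lipoprotein receptor Scarb1, and the single higher member was Por, the electron donor of microsomal P450 enzymes, at 0.55 (SE 0.143, adjusted p = 0.000848, exact conditional binomial test). Cyp17a1, needed for androgens and cortisol, had 7 reads in replicate 1 and 4 in replicate 2. The list median was -1.03, below all 10000 matched random lists, and was -0.78 under TMM, -0.79 under DESeq2 and -0.44 under spike-in scaling, while the median of all genes tested was -0.28, -0.03, -0.04 and 0.31.

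X zone genes were lower in replicate 2, while genes of the zona glomerulosa and capsule went both ways. In the X zone, the transient inner cortex of young mice, Akr1c18, which inactivates progesterone, had 10261 reads in replicate 1 and 2247 in replicate 2 (log2 ratio -2.02, SE 0.034). Cyp2f2 had 1432 and 568 reads (-1.16) and Pik3c2g 93 and 24 (-1.76). All 3 were lower in replicate 2, over all genes and adjusted over the list alone, while Nr0b1 with 51 and 32 reads did not pass (-0.49, exact adjusted p = 0.270). Thrb had 4 and 6 reads and Sult1e1 1 and 0, too few to compare. The X zone list took 1.11% of gene reads in replicate 1 and 0.304% in replicate 2. In the list for zona glomerulosa and capsule, 5 of 14 measured members were higher and 2 lower in replicate 2, also when adjusted over the list alone. The matrix genes Col3a1 (493 and 1325 reads, log2 ratio 1.60, SE 0.076) and Col1a1 (164 and 375 reads, 1.36, SE 0.135) were higher, whereas Cyp11b2, the aldosterone synthase (347 and 161 reads), was lower at -0.93 (SE 0.137). Dab2 had 274 and 226 reads and did not pass (-0.11, exact adjusted p = 0.609). The list median of 0.08 stood at percentile 98.0 of random lists, and was 0.33 under TMM and 0.67 under spike-in scaling.

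Chromaffin genes of the medulla were lower in replicate 2 without exception among those that passed. They took 1.47% of gene reads in replicate 1 (95% interval 1.44 to 1.49) and 0.576% in replicate 2 (0.561 to 0.592). Of 23 measured members 17 were lower and 0 higher, with the same counts adjusted over the list alone. Chgb, a granule protein (4738 and 1685 reads), had a log2 ratio of -1.32 (SE 0.041), Chga (4347 and 1491 reads) of -1.37 (SE 0.043), Th, the rate-limiting enzyme of catecholamine synthesis (2168 and 661 reads), of -1.54 (SE 0.064), and Scg2 (1522 and 560 reads) of -1.27 (SE 0.071). The list median was -1.32, below all 10000 random lists, and was -1.07 under TMM and -0.73 under spike-in scaling.

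Transcripts typical of liver were far more abundant in replicate 2. Alb, which encodes albumin (ENSMUSG00000029368.10, chromosome 5, 90460897 to 90476602), had 158 reads in replicate 1 and 17770 in replicate 2, a ratio of 127 (95% counting interval 108 to 149). Apoa1 had 93 and 8290 reads (log2 ratio 6.64, SE 0.150), Ttr, which encodes transthyretin, 32 and 3453 (6.90, SE 0.254), and Apoa2 37 and 3447 (6.69, SE 0.237). The fixed list for liver and pancreas took 0.0396% of gene reads in replicate 1 (95% interval 0.0359 to 0.0436) and 3.83% in replicate 2 (3.79 to 3.87), a ratio of 96.7. Of its 8 measured members 7 were higher in replicate 2, over all genes and adjusted over the list alone, with a median of 6.71. Cela1 did not pass (46 and 25 reads), and the pancreatic genes Prss2, Cpa1, Ctrb1 and Pnlip had 0 reads in both libraries, which allows up to 2.82 and 3.17 CPM. In the hepatocyte set added after the data had been seen, all 26 measured genes were higher in replicate 2, by a median of 6.62 or 6.58 with genes at 0 reads set at their bound. In the skeletal muscle set, also added afterwards, all 14 measured genes were higher, by a median of 4.47 or 4.30 at the bound, and the set took 0.0137% and 0.307% of gene reads. Acta1, the actin of skeletal muscle, had 30 and 758 reads, and Ckm, the muscle creatine kinase, 25 and 477.

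Genes of other cell types went in different directions. Adipocyte genes took 0.799% and 0.953% of gene reads with a list median of 0.33, and 4 of 9 measured members were higher in replicate 2 and 0 lower, or 4 and 1 adjusted over the list alone. Ucp1, the uncoupling protein of brown fat (1617 and 1964 reads), had a log2 ratio of 0.45 (SE 0.048) and Cidea (1979 and 2223 reads) of 0.34 (SE 0.045), while Fabp4 (3047 and 2686 reads) and Cfd (619 and 547 reads) did not pass at -0.01 each, values that turn positive under the 3 other scalings. Erythroid genes were lower in replicate 2 in 5 of 5 measured members, also adjusted over the list alone, with a median of -1.64. The globin genes Hba-a1 (6195 and 1748 reads), Hbb-bs (3292 and 937), Hba-a2 (1689 and 470) and Hbb-bt (683 and 208) are near-identical in pairs and uncertain singly. Of 13 endothelial genes 1 was lower in replicate 2, Plvap (352 and 179 reads, log2 ratio -0.80), also when adjusted over the list alone, with Cldn5 (260 and 194 reads), Eng (151 and 151) and Egfl7 (148 and 108) not passing and a list median of 0.07. Of 8 measured leukocyte genes 3 were higher, or 5 adjusted over the list alone, with a list median of 0.73, among them Cd74 (71 and 99 reads, log2 ratio 0.65) and H2-Ab1 (20 and 41 reads, 1.19), while Lyz2 (48 and 67 reads, 0.65) and C1qc (24 and 37 reads, 0.78) did not pass over all genes. Under spike-in scaling the medians were 0.91 for adipocyte, -1.05 for erythroid, 0.66 for endothelial and 1.32 for leukocyte genes, and Plvap no longer passed. Spp1 was the single kidney-list gene measured, with 166 reads in replicate 1 and 77 in replicate 2 (-0.93), lower also when adjusted over the list alone but not passing under spike-in scaling. Of Schwann and sustentacular genes S100b (42 and 45 reads) and Mbp (15 and 12) were measured and did not pass, while Fabp7 (7 and 5 reads) and Erbb3 (1 and 8) were below the minimum. Xist, which is expressed from the inactive X chromosome of females, had 14 and 19 reads and its antisense partner Tsix 18 and 14. The longest annotated Xist transcript has 17946 nt, while the longest Xist models had 2166 nt in replicate 1 and 475 nt in replicate 2. Single-exon reads of Xist and Tsix would be of uncertain strand. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 0 reads in both libraries.

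Most nuclear-encoded respiratory chain genes did not pass the test under scaling by total reads. Of 28 measured 9 were higher in replicate 2, 1 lower and 18 not called, adjusted over all genes or over the list alone, with a median of 0.07 at percentile 98.2 that became 0.32 under TMM and DESeq2 and 0.66 under spike-in scaling. Atp5b, the beta subunit of ATP synthase (5163 and 5471 reads), had a log2 ratio of 0.25 (SE 0.028) and Atp5a1 (2671 and 2561 reads) of 0.11 (SE 0.040), while Ndufa4 (2561 and 2077 reads) was the lower one at -0.13 (SE 0.043), a direction that turns under the 3 other scalings. Cytosolic ribosomal protein genes were lower in 24 of 25 cases, with the same count adjusted over the list alone, among them Rpl41 (1264 and 732 reads, -0.62), Rplp0 (1212 and 741, -0.54), Rpl5 (1193 and 736, -0.53) and Rpl3 (1126 and 692, -0.53). Their median of -0.54 stood at percentile 0.64 and became 0.05 under spike-in scaling, which turns the sign. Rpl41, Rplp0, Rpl5 and Rpl3 fell short of the threshold at an assumed coefficient of variation of 0.2. Immediate early and stress genes were lower in 9 of 13 cases, or 10 adjusted over the list alone, with a median of -1.08, below all 10000 random lists. Junb (376 and 119 reads, -1.48), Nr4a1 (299 and 125, -1.08) and the chaperone Hspa5 (1167 and 790, -0.39) were lower, with Hspa5 turning to 0.20 under spike-in scaling, and Ier2 (187 and 141 reads) did not pass.

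Cholesterol synthesis genes were lower in 7 and higher in 2 of 20 cases, or 8 and 2 adjusted over the list alone. Dhcr7, which makes cholesterol from its last precursor (852 and 200 reads), had a log2 ratio of -1.92 (SE 0.113), Msmo1 (307 and 103 reads) of -1.40 and Hmgcs1 (438 and 310 reads) of -0.33, the last turning to 0.26 under spike-in scaling, while Insig1 (189 and 154 reads) did not pass. Proliferation genes were lower in 7 of 15 cases over all genes and over the list alone, among them Mcm2 (177 and 116 reads, -0.44) and Rrm2 (181 and 104, -0.63). Mcm6 (169 and 152 reads) and Ccnb2 (99 and 67) did not pass, and Mcm2 turned to 0.15 under spike-in scaling. Both Mcm2 and Rrm2 fell short of the threshold under TMM, DESeq2 and a coefficient of variation of 0.2, and Rrm2 also under spike-in scaling. Of 14 imprinted growth genes 7 were lower and 2 higher, also when adjusted over the list alone. Dlk1 (546 and 189 reads, -1.36), Cdkn1c (1203 and 746, -0.52) and Gnas (2745 and 2192, -0.15) were lower, though Gnas turned positive under the 3 other scalings and Cdkn1c under spike-in scaling. H19, a maternally expressed RNA of fetal tissues, was higher with 22 and 613 reads (4.94, SE 0.310). The neighbouring Igf2 had 0 and 44 reads, 16.5-fold higher in replicate 2 against the limit of 3 counts. These were the only higher members, beside medians of 6.62 in the hepatocyte and 4.47 in the skeletal muscle set. Antioxidant genes split, with 3 of 19 gene entries higher and 6 lower, or 5 and 6 adjusted over the list alone. Prdx1 (1503 and 1493 reads, 0.16) and Gpx1 (536 and 736, 0.63) were higher, and Prdx2 (1107 and 590, -0.74) and Gpx4 (994 and 646, -0.45) lower, Gpx4 turning to 0.14 under spike-in scaling. Of 11 mitochondrially encoded genes 1 was lower over all genes and 0 over the list alone. This was mt-Cytb (232 and 156 reads, -0.40), which turned to 0.19 under spike-in scaling, and mt-Co1 (734 and 591 reads), mt-Nd2 (76 and 68) and mt-Nd1 (69 and 69) did not pass. Their median was -0.08, that of imprinted genes -0.30, of proliferation genes -0.39, of cholesterol synthesis -0.38 and of antioxidant genes -0.04, and all 5 are positive under spike-in scaling, the mitochondrial and antioxidant ones under TMM and DESeq2 too.

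**Figure D1:**
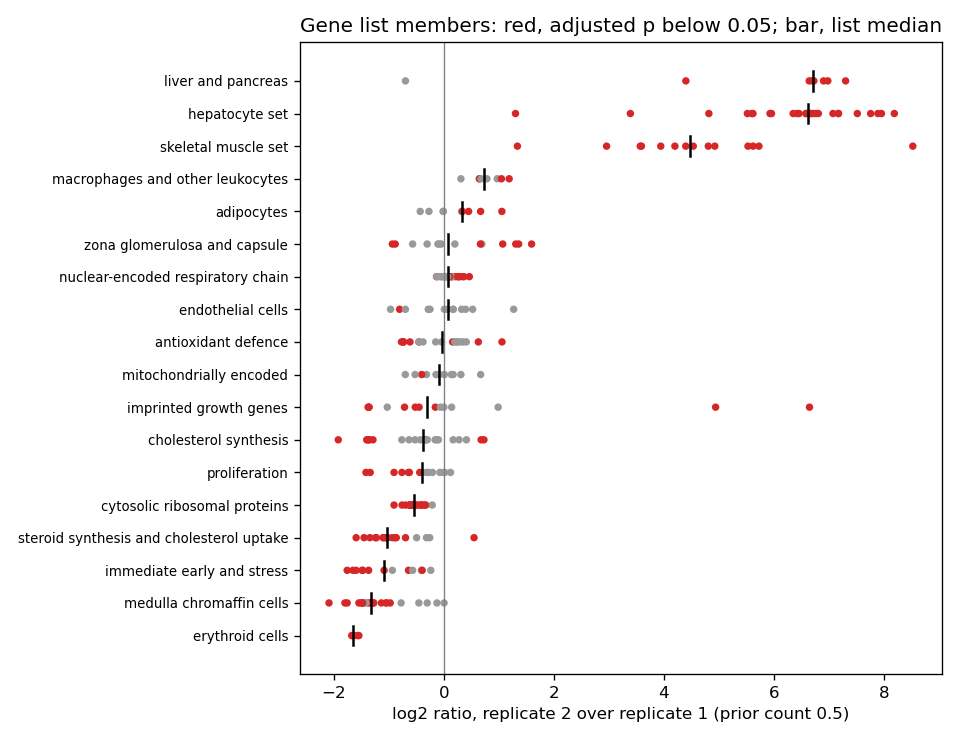
Log2 ratio of CPM in replicate 2 over replicate 1 for each measured member of the gene lists (points, red where the adjusted p is below 0.05) with the list median (bar). The chromaffin and steroid medians lie at -1.32 and -1.03 and the liver median at 6.71.

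Over all annotated genes, 2436 of 9211 tested (26.4%) differed between the libraries by the exact conditional binomial test at an adjusted p of 0.05, 790 higher and 1646 lower in replicate 2. Large differences were mostly in the first direction, with 305 genes over 16-fold higher and 5 over 16-fold lower, by ratios with 0.5 reads added. Against the limit of 3 counts, genes with 0 reads in a library may fall short of 16-fold. Those 305 genes held 0.168% of gene reads in replicate 1 and 15.5% in replicate 2. The split depended on the scaling. TMM gave 1093 higher and 643 lower, DESeq2 size factors 1075 and 656, and spike-in reads 2071 and 170, so that the share of calls that were higher in replicate 2 went from 32.4% to 63.0%, 62.1% and 92.4%. With an assumed coefficient of variation of 0.2 between replicates, edgeR's exact test called 513 genes, 446 higher and 67 lower, without Cyp11a1, Cyp21a1, Hsd3b1 and Cyp11b1. The assumed 0.2 lies below the 0.466 estimated from this pair, which counts every difference between the libraries as spread. Across genes, log2 CPM correlated between the libraries with Pearson's r = 0.72 and CPM with Spearman's rho = 0.796, over genes that are not independent replicates.

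**Figure D2:**
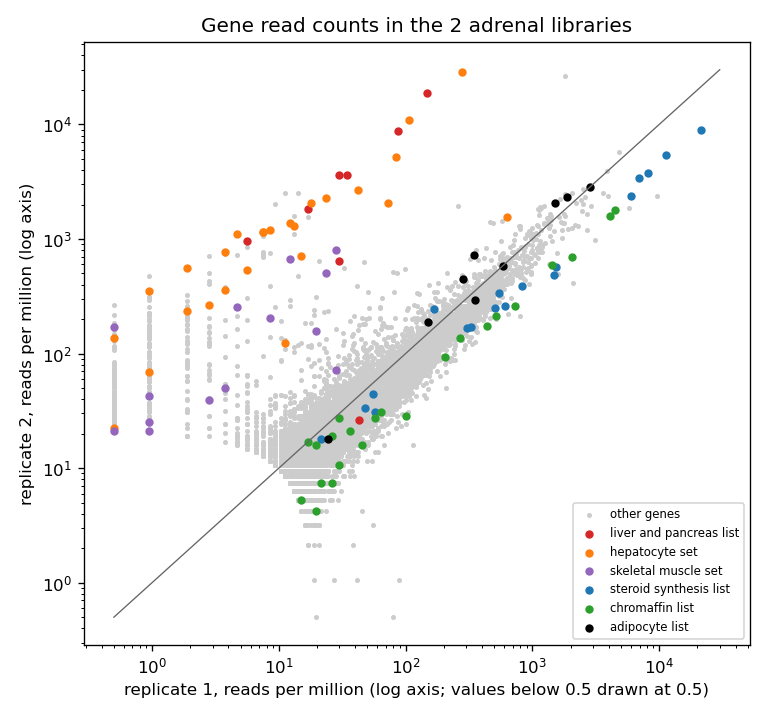
CPM of each annotated gene in replicate 1 (horizontal, log scale) and replicate 2 (vertical, log scale), with values below 0.5 drawn at 0.5. Most genes of the liver and hepatocyte lists lie far above the diagonal and most of the steroid and chromaffin lists below it.

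Among the 10 genes with the largest ratios towards replicate 2 were Elovl2, Ugt2b36, Akr1c6, Myh1, Spp2, Prodh2, Uox, Hao1 and Hsd17b13. Apart from Myh1, a myosin of fast skeletal muscle fibres, they are known from liver. All of these but Uox had 0 reads in replicate 1, so their rank rests on the 0.5 reads added. Their folds against the limit of 3 counts, from 50.3-fold for Hsd17b13 to 77.3-fold for Elovl2, do not place them above Alb with its ratio of 127. Myh1 had 0 reads in replicate 1 and 163 in replicate 2, 61.2-fold higher against that limit, with a counting interval from 49.2-fold. Hsd17b13 had 0 and 134, 50.3-fold higher, with an interval from 40.3-fold. Uox, the urate oxidase, had 1 and 449 reads, a ratio of 505 with a counting interval of 90.3 to 20008. Towards replicate 1 the leading genes were AC154200.1, Usp50, Lck, Ly6k, Tbx3os1, Akr1b7, Bex2, Pdlim4, Snora57 and Emb. Akr1b7, an aldose reductase of the adrenal cortex, carried most reads among them, 2213 and 389 (log2 ratio -2.34, SE 0.079). AC154200.1, a lincRNA on chromosome 17 at 17340820 to 17346140, had 84 and 0 reads, all of the Genomic class. Against the limit of 3 counts it was 24.9-fold lower in replicate 2, with a counting interval of the ratio up to 0.0505. Usp50 had 94 and 1 reads, also all Genomic, a ratio of 0.0120 (counting interval 0.000300 to 0.0684). Snora57 reads were all Genomic in both libraries, and Tbx3os1 reads were so for 91.7% in replicate 1 and 60% in replicate 2. Lck, a kinase of T cells, had 59 and 3 reads, a ratio of 0.0572 (0.0115 to 0.176). Of the leukocyte list, Cd3e had 1 and 0 reads and Ptprc 1 and 2.

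Most reads matched annotated transcripts. Known models took 72.6% of reads without spike-ins in replicate 1 and 75.9% in replicate 2, 74.2 ± 2.31% (SD, n = 2). ISM reads made up 10.3% in both (Fisher's exact p = 0.964), mostly chains that lacked the 5' end, 67.8% and 65.8% of ISM reads. NIC took 4.34% and 3.86%, NNC 3.18% and 3.02%, Genomic 5.25% and 4.10%, Antisense 3.69% and 2.43%, and Intergenic 0.626% and 0.417%. All classes but ISM differed between the libraries beyond counting error, the least clear being NNC (Fisher's exact test, adjusted p = 1.65e-10). Steroid genes varied in class. Hsd3b1 had 85.3% and 86.3% of its reads as ISM and 0.197% and 0.280% as Known, and of Cyp11a1 reads 48.0% in replicate 1 and 43.6% in replicate 2 lay in single-exon models. Nearly all of those in replicate 1 were classed Genomic, 10897 of them in 1 model, while replicate 2 had 0% of Cyp11a1 reads as Genomic and 51.9% as ISM, 3723 of them in 1 single-exon model. The Genomic difference and the equal ISM shares therefore depend in part on how these reads were classed.

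**Figure D3:**
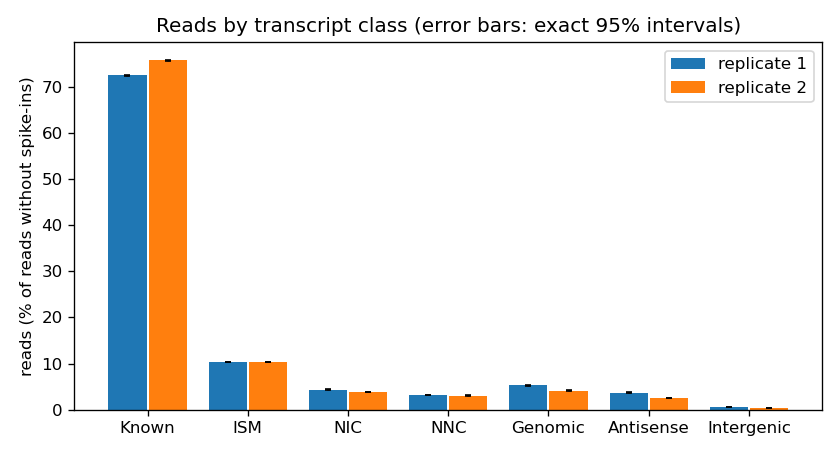
Share of reads without spike-ins (%) by transcript class for replicate 1 and replicate 2, with exact 95% intervals. Known models hold 72.6% and 75.9%, and no other class exceeds 10.3%.

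ERCC spike-ins took 2.35% of all reads in replicate 1 (95% interval 2.32 to 2.38) and 1.60% in replicate 2 (1.58 to 1.63), with reads on 55 and 47 of the 96 species. Both libraries detected 14263 of 18111 genes (78.8%), fewer than the 14704 to 14823 given by 100 random splits of the pooled reads. Among genes with at least 20 summed reads, 99 were seen in replicate 2 alone and 2 in replicate 1 alone.

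Isoform use was close between the libraries, with a median difference of 3.15 percentage points in the share of the leading isoform. Of 5306 genes with at least 20 Known, NIC or NNC reads in each library, 1273 (24.0%) had a second isoform at 10% or more in both, and 2178 had a leading isoform above 90% in both. The 8 with most reads were Apoa2, Sparc, Acly, Gnas, Cox4i1, Pkm, Scg2 and Hadhb. Acly, the citrate lyase that supplies acetyl-CoA to lipid synthesis, had 63.2% and 64.4% of its reads on Acly-201 and 29.97% and 30.5% on Acly-203, which includes a 30 nt exon at chromosome 11, 100503160 to 100503189. Gnas, the stimulatory G protein alpha subunit, had 57.4% and 58.7% on Gnas-208, which includes a 45 nt exon at chromosome 2, 174336747 to 174336791, and 20.2% and 20.2% on Gnas-207, which lacks it. Pkm, pyruvate kinase, had 79.4% and 69.7% on Pkm-201 and 14.97% and 21.5% on Pkm-202, which use different 167 nt exons at 59675568 and 59675029 on chromosome 9. Scg2 had 50.2% and 54.3% on Scg2-202, which removes a 120 nt intron from the last exon of Scg2-201 (48.6% and 43.5%). Cox4i1 had 58.2% and 58.5% on Cox4i1-204, Sparc 51.1% and 52.1% on Sparc-201, Hadhb 46.6% and 50.2% on Hadhb-203, and Apoa2 51.4% and 50.5% on Apoa2-204, from 35 reads in replicate 1. Cox4i1-204 has no intron that Cox4i1-201 lacks, and Sparc-205 (30.9% and 31.4%) none that Sparc-201 lacks. Reads of the longer transcript without their 5' end would therefore count for the shorter. The 1273 genes were not screened for such pairs.

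In the panel of 30 adrenal and splicing genes, 22 were lower and 2 higher in replicate 2 as genes, or 23 and 2 adjusted over the list alone, with a median of -0.72 that became -0.47 under TMM and DESeq2 and -0.13 under spike-in scaling. Of these 29 had at least 50 reads in each library. In 14 the leading isoform held over 90% in both, as in Star (98.0% and 97.9%), Th (95.9% and 96.4%) and Chgb (99.2% and 98.9%), and in 10 a second isoform was in use. Averaged over both libraries, the leading share was lowest in Pam, which amidates peptide hormones (16.5% and 21.1%), followed by the splicing factor Srsf5 (37.2% and 16.9%, below an unannotated chain with 25.4% in replicate 2), Hsd3b1 (34.8% and 36.5%, from 132 and 52 reads), H2afy (37.4% and 40.3%), Hnrnpa2b1 (48.4% and 44.1%) and Rps24 (47.7% and 51.5%). Between the libraries 6 panel genes differed in isoform shares, Cyp11a1, Gnas, Pkm, Tpm1, Tpm3 and Srsf5.

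Isoform shares differed between the libraries in 56 of 2709 genes tested (2.07%). In Hsd11b1, which regenerates active glucocorticoid, Hsd11b1-201 held 7.69% of the tested reads in replicate 1 and 89.1% in replicate 2, and Hsd11b1-205, whose first exon lies across an intron of 21659 nt, led in replicate 1 (permutation p = 1e-05, the smallest possible, adjusted p = 0.00111). Hsd11b1-201 has no intron that Hsd11b1-205 lacks, so reads of Hsd11b1-205 without their 5' end would count for Hsd11b1-201. In Khk, ketohexokinase, Khk-204 held 3.33% and 79.7%, and it includes a 135 nt exon at chromosome 5, 30927022 to 30927156, that Khk-203 skips. Tpm2-202, a tropomyosin transcript with a 76 nt exon at chromosome 4, 43518644 to 43518719, in place of one in Tpm2-203, held 0% and 64.2%. Fpgs-201 held 100% and 27.8%, against an unannotated transcript that starts at an exon at chromosome 2, 32704086 to 32704145, and in Fggy an unannotated transcript with a first exon at chromosome 4, 95579421 to 95579554, held 0% and 62.7%. Of the 56 genes 21 (37.5%) were also higher in replicate 2 as genes and 14 lower, against 157 (5.92%) higher and 792 lower among the other 2653 genes tested.

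**Figure D4:**
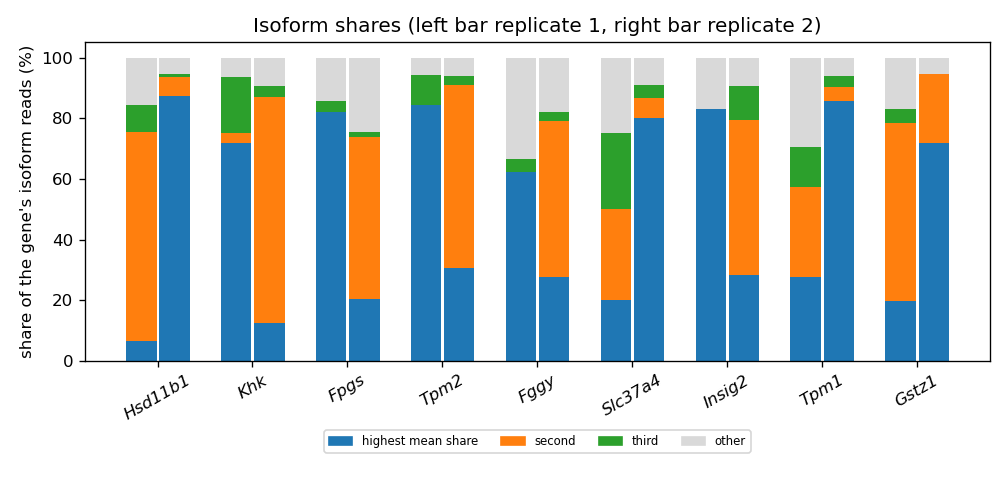
Share (%) of each gene's Known, NIC and NNC reads held by its transcript of highest mean share (blue), the second (orange), the third (green) and all others (grey), with the left bar of each pair for replicate 1 and the right bar for replicate 2. Hsd11b1-201 holds 6.67% and 87.2%, Khk-204 3.13% and 74.5%, and Fpgs-201 82.1% and 20.5%.

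Unannotated transcripts were numerous and mostly seen once. NIC and NNC chains numbered 42893 in replicate 1 and 34930 in replicate 2, and 78.4% and 79.3% of them had 1 read. Both libraries held 9978, 23.3% of those in replicate 1 and 28.6% of those in replicate 2, and these carried 53.5% and 54.6% of the reads of such chains. The most read was a 5-exon chain of Oaz1, the ornithine decarboxylase antizyme, at chromosome 10, 80826656 to 80829290, with 1806 and 1243 reads, 95.0% and 95.4% of the gene's reads, all on annotated splice sites. Chains of Phb2 (377 and 300 reads), Oaz2 (348 and 224 reads), Idh3g (360 and 300 reads) and Mrpl33 (354 and 206 reads) followed. The Idh3g chain has 1 unannotated intron at chromosome X, 73782104 to 73782670, of which one end lies 4 nt from an annotated splice site, and the Mrpl33 chain has one at chromosome 5, 31614031 to 31616380, with one end 8 nt away.

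Unannotated loci after merging numbered 23341, of which 5900 (25.3%) had reads in both libraries, and 94.1% and 93.5% of their reads were single-exon. The largest, on the minus strand of chromosome 17 at 39843013 to 39848035, overlaps rRNA and lincRNA genes and had 1270 and 1018 reads. Others among the 5 with most reads were a locus antisense to Actb at chromosome 5, 142900970 to 142903654 (569 and 236 reads), one antisense to the lincRNA Tmem250-ps at chromosome 2, 26136814 to 26138383 (440 and 267 reads), and one antisense to Sept2 at chromosome 1, 93507726 to 93509733 (322 and 226 reads). The last 3 are single-exon, so their strand is uncertain.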

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

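No test was made of the signal below, and the loci on chromosome Y were looked at only after the data had been seen. Although the labels give female animals, reads placed on chromosome Y numbered 193 in replicate 1 and 94 in replicate 2, 0.0169% (95% interval 0.0146 to 0.0194) and 0.00948% (0.00766 to 0.0116) of all reads, above the limit that a count of 0 allows. Of these reads 6 and 1 lay in annotated genes, and the listed Y-linked genes had 0 reads in both libraries. The largest of the unannotated loci there, on the minus strand of chromosome Y at 43918754 to 43923547 with up to 3 exons, held 126 of the reads in replicate 1 and 70 in replicate 2.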

How the results depend on the processing

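Chosen only after the data had been seen were each library's own class for isoforms, with 67 of 2703 genes differing and 1258 genes with 2 or more isoforms in use, other random seeds for the isoform test, and list shares over reads without liver and muscle genes, where 18 shares moved by less than the spread between the libraries and 2 by more. The cause was not tested for any change below unless it is given.

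The number of genes differing between the 2 libraries stayed within 1.5 times of 2436 under 7 alternatives, from 1731 to 2300, but its split moved. Lower in replicate 2 were 643 genes under TMM, 656 under DESeq2 and 170 under spike-in scaling, and higher were 2071 under spike-in scaling, since these scalings shift every log2 ratio upwards. With at least 100 summed reads 470 were higher, as 3901 genes were tested. With an assumed coefficient of variation of 0.2, 513 genes differed (446 higher and 67 lower), all among the 2436. Of 810 values of 104 named genes over the alternatives, 717 kept direction and side of the threshold, 55 fell short of it, 14 newly passed it and 24 reversed. Short of the threshold fell 32 genes at a coefficient of variation of 0.2 (Mcm2, Prdx2, Rrm2, Cyp11b2, Nr4a1, Cyp21a1, Cidea, Cd74, Atp5b, Atp5a1, Hspa5, Gnas, Hsd3b1, Prdx1, Spp1, Ndufa4, Ucp1, Cyp11a1, Plvap, Cdkn1c, Cyp2f2, Rpl5, Rpl3, Gpx1, mt-Cytb, Rplp0, H2-Ab1, Adh1, Cyp11b1, Gpx4, Rpl41 and Hmgcs1), and Mcm2, Rrm2, Hspa5, mt-Cytb and Hmgcs1 under TMM and DESeq2, Prdx2, Rrm2, Spp1, Plvap and Rpl41 under spike-in scaling, Cd74, Atp5a1, Hsd3b1, Prdx1 and Pik3c2g with Known reads only, Mcm2 and mt-Cytb with no count minimum, and mt-Cytb with thinned reads. Reversed to positive were Gnas (0.10), Ndufa4 (0.12), Cfd (0.24) and Fabp4 (0.24) under TMM and Gnas (0.091), Ndufa4 (0.11), Cfd (0.24) and Fabp4 (0.23) under DESeq2. Under spike-in scaling these were Mcm2 (0.15), Dab2 (0.48), Hspa5 (0.20), Gnas (0.43), Ndufa4 (0.46), Cdkn1c (0.069), Insig1 (0.46), Rpl5 (0.062), Rpl3 (0.056), Cfd (0.58), Fabp4 (0.58), mt-Co1 (0.45), mt-Cytb (0.19), Rplp0 (0.049), Gpx4 (0.14) and Hmgcs1 (0.26). The steroid, chromaffin and liver medians kept their direction under TMM, DESeq2 and spike-in scaling.

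The share of Known reads became 82.8% when only transcripts with at least 5 reads counted. The genes differing in isoform shares between the 2 libraries numbered 35 of 1675 with Known transcripts only, of which 31 were among the 56, and 55 to 56 over 4 random seeds. The genes with 2 or more isoforms in use numbered 266 of 1397 with at least 100 reads in each library, 611 at 20% or more, and 1824 to 2035 in 1 library alone. Unannotated chains seen in both libraries numbered 1032 at 5 reads per library, 0 by the identifiers of the tables, which do not recur between them, and 34930 to 42893 in 1 library alone, where no second library is asked for. Differences between the libraries have no value with 1 library left out. Depth limits rare transcripts, as 0 reads allow up to 2.82 and 3.17 CPM and most unannotated chains had 1 read.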

Other observations

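The tests of scaling, liver material, dilution and adrenal share were chosen only after the results had been seen, those of muscle reads and single-exon models before, though Cyp11a1 had been seen as an example, and the loci and genes named here were picked after their values had been seen.

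Some unannotated loci include spliced models and lie opposite annotated genes. How many of their reads are spliced was not counted, and 94.1% and 93.5% of the reads of all unannotated loci were single-exon, with uncertain strand. A locus with up to 4 exons antisense to Mc2r, the receptor for the pituitary hormone ACTH, at chromosome 18, 68402601 to 68429320, had 274 reads in replicate 1 and 104 in replicate 2, a ratio of 0.427 (counting interval 0.338 to 0.537), against 61 and 29 reads of Mc2r itself. One antisense to Camk2b, a calcium-dependent kinase, at chromosome 11, 6005800 to 6011665, with up to 2 exons had 124 and 300 reads (2.72, interval 2.20 to 3.39). An intergenic locus with up to 3 exons at chromosome 13, 55184770 to 55189155, had 221 and 65 reads (0.331, interval 0.247 to 0.438).

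A few genes with long transcripts, picked by their values, had few reads. Apob, whose longest annotated transcript has 13934 nt, had 0 and 5 reads beside 93 and 8290 of Apoa1 (1035 nt), and Ttn (106824 nt) and Neb (22489 nt) had 0 and 1 reads each beside 30 and 758 of Acta1 (1446 nt), whereas the muscle myosin Myh1 had 0 and 163. Models longer than 5000 nt held 3.14% of reads in replicate 1 and 3.45% in replicate 2.

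Liver transcripts were far higher in replicate 2 than in replicate 1, with smaller differences in Apoc1 (673 and 1476 reads) and G6pc (12 and 116 reads). Scaling by total reads is argued against. Another scaling shifts every log2 ratio alike, so it cannot move the liver list median of 6.71 without moving all genes. That median was 6.95 or more under TMM, DESeq2 and spike-in scaling, beside -0.03, -0.04 and 0.31 for all genes tested. A candidate explanation is liver cells or liver RNA in the replicate 2 material, which needs at least 80% of the measured hepatocyte genes over 4 log2 units higher, and 92.3% (24 of 26) were, although this was seen and tested on the same data. Passage of reads from replicate 2 into replicate 1, as a source of the low liver counts there, cannot be told apart from muscle genes expressed in replicate 1, since 146 muscle reads were found against 2906 in replicate 2, where the liver ratio gives 54.4 (40 to 69) over all 34 measured liver and hepatocyte genes (1.87%, 1866 against 99675 reads) or 33.6 (23 to 45) over the 31 of them more than 4 log2 units higher, without Apoc1, G6pc and Cela1 (1.16%, 1135 against 98058 reads), which meets the outcome set down for passage, while the reading of an excess as open was made after it was known. A difference between the tissue samples themselves stays open, and no biological explanation was tested, as the design has 1 group.

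Cortex and chromaffin genes were lower in replicate 2. Dilution by liver RNA alone would lower both lists alike. It is argued against, since the adipocyte median lay 1.36 above the steroid median, or 1.19 above it without Pck1. This does not argue against dilution as a part of the cause. Shuffling genes between the lists gave an exact permutation p = 0.000458 over 4686825 arrangements. The genes are not independent replicates, so this p measures no spread between libraries. Scaling by total reads as the whole cause is argued against by a steroid median no nearer to 0 than -0.44. A smaller share of adrenal tissue among several tissues stays a candidate for part. The chromaffin median differed from the steroid median by -0.29, within the 0.5 asked for (permutation p = 0.0466 over genes, 100000 draws). The liver, muscle and adipocyte medians were not lower. All these medians were known when the test was set down, so meeting it lends no support of its own. A smaller adrenal share would leave unaccounted the larger differences of X zone and erythroid genes and the spread of steroid genes from -1.59 to 0.55. A difference within the adrenal glands of these animals thus stays open, untested.

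Single-exon reads of one gene were often given different classes in the 2 libraries. Of 1377 genes with overlapping leading single-exon models, 278 (20.2%) had one called Genomic in one library and ISM in the other, as in Cyp11a1, a Genomic model of 4008 nt with 10897 reads in replicate 1 and an ISM model of 1946 nt with 3723 reads in replicate 2. The hypothesis that a longer read changes the class of a model asks for the Genomic model to be the longer in most genes, and it was so in 25.5% (71 of 278, 95% interval 20.5 to 31.1), with median lengths of 1165.5 nt for Genomic and 1508 nt for ISM models. This meets the outcome set down against the hypothesis. Model length was later seen not always to record the length of the reads, since in 26 of the 278 genes a model was under 50 nt, the shortest 1 nt. These 26 are a minority, but whether the other models record the length of their reads is not known. The values show that the Genomic model was not the longer in most of these genes. They cannot tell which library held the longer reads, so the hypothesis stays open.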
